A study of Mus musculus with 4 samples.

How the data were processed

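Liver nonparenchymal cells of 4 wild-type male mice were profiled by single-cell RNA sequencing on a cartridge platform with whole-transcriptome amplification (BD Rhapsody). The 2 CCl4 mice were given CCl4 mixed 1 to 9 with corn oil, at 10 µl per g of body weight, and the 2 corn oil mice the vehicle. Per the labels, livers were perfused with pronase and collagenase, hepatocytes were removed by a spin at 50 × g, a density gradient removed dead cells and erythrocytes, samples had a viability over 70%, and about 10000 viable cells were loaded per mouse and sequenced on a DNBSEQ instrument. Per the file headers, reads had been aligned and counted with the BD WTA Rhapsody Analysis Pipeline, version 1.9.1, against GRCm38 with GENCODE vM19, and the deposited values are molecule counts (UMIs) per cell and gene after the pipeline's error correction of molecular barcodes. The aligner is not given in the sources used here. The deposited tables hold the cells that the pipeline had called, the smallest with 1604 UMIs. The labels place all 4 samples in 1 batch, while the headers show that the CCl4 1 table was produced in a separate run from the other 3, so a run effect cannot be separated from that mouse. Raw reads were not used here.

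The 4 tables held 27091 cells. Cells with at least 200 genes and at most 25% of UMIs from mitochondrial genes were kept, which left 6852, 7247, 6141 and 5621 cells in corn oil 1, corn oil 2, CCl4 1 and CCl4 2. The median share of mitochondrial UMIs before the filter was 7.77%, 9.78%, 7.46% and 8.60%. Doublets were scored per library by the Scrublet method, written anew from its description with 2 simulated doublets per cell, and the 5% of cells with the highest score in each library were removed. The remaining cells were clustered together on 2000 variable genes and 30 principal components, with a shared-neighbour graph of 15 neighbours and Leiden clustering at resolution 1 with random seed 1. No integration of libraries was applied. Work was done in Python 3.11.15 with numpy 2.4.6, scipy 1.17.1, pandas 2.3.3, scikit-learn 1.9.0, leidenalg 0.10.2 and matplotlib 3.10.9.

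Clusters were named from 17 sets of marker genes. A set counted where at least 3 of its markers were detected in at least 25% of the cells of the cluster. A cluster was left unnamed as mixed where the score of a different lineage reached 0.3 of the best score, and as ambiguous where another type of the same lineage reached 0.7 of it, with the 10 leading genes of each cluster checked. The marker sets, filters, gene lists, tests and all alternatives but those named below were chosen before the data were examined. The naming thresholds, the joining of T with NK cells into 1 class, and the rule for mixed clusters were set after the clusters had been seen. Clusters are numbered by size from 0. The cholangiocyte class had 12 cells in corn oil 1 and was not tested for gene expression, which required 20 cells in every library, so 7 classes were tested. Neutrophils, B cells, mesothelial cells and hepatocytes were found only in clusters that also carried endothelial markers and were not analysed as classes. The 4 gene lists for B cells and hepatocytes were therefore not tested.

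For each class, UMIs were summed per mouse and tested with the quasi-likelihood test of edgeR 4.0.16 in R 4.3.3, with TMM normalization, the filterByExpr filter on low counts and Benjamini-Hochberg adjustment over the genes of the class. A gene is called at an adjusted p under 0.05. The sums held 2806389 to 5235412 UMIs per mouse in Kupffer cells, 305453 to 791148 in T/NK cells, 244567 to 1259281 in conventional dendritic cells, 835696 to 8806885 in monocyte/macrophage cells, 203056 to 584668 in plasmacytoid dendritic cells and 836614 to 4683591 in stellate/fibroblast cells. Shares were tested with edgeR on cell numbers with all named cells as library size, adjusted over classes, beside an exact two-sided permutation test over the 6 splits of the mice. The difference of the CCl4 effect between 2 classes was tested as an interaction with mouse as a block. Gene lists were tested with camera of limma 3.58.1 at a preset inter-gene correlation of 0.01 on voom log2 CPM, beside camera with an estimated correlation and fry, adjusted over the lists of a class, where at least 5 members were measured. Of 80 list tests, camera called 47. With an estimated correlation 0 of these were called, with a lowest adjusted p of 0.13, and fry called 13 of the 47 (2 in Kupffer, 6 in monocyte/macrophage and 5 in stellate/fibroblast cells). The list calls therefore depend on the form of the test. A higher correlation between genes is not the only reason. For Kupffer identity genes the estimated correlation was -0.0231, below the preset, yet the unadjusted camera p went from 1.04e-10 to 0.0185. In 4 lists a gene had no UMI in 1 group, and putting such genes at their bound changed no list median by more than 0.0001.

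Genes are named by a rule. In each class these are the called genes with both CCl4 mice on one side of both corn oil mice and a mean of at least 50 CPM in the higher group. Predicted genes, immunoglobulin and T cell receptor segments and hepatocyte transcripts were not named. They were ranked by fold change, up to 10 higher and 10 lower in the 4 largest classes and 4 and 4 in the others, with up to 4 called members of each list by fold change, or the 2 members with the highest mean where none was called. The text prints these from the top of each ranking, except for 1 gene that is not reported here. CPM are scaled by the TMM factors. Where a group held 1 to 3 UMIs the ratio of pooled counts is given with its 95% counting interval, and where it held none a bound with a floor of 3 UMIs over the group. Of such genes no fitted fold is printed, except where the alternative without cluster 22 left few UMIs, and without the mouse that held the few UMIs it has no limit. Of 25149 symbols, 24957 matched the gene table used for loci (GENCODE vM21, GRCm38). Members of families with close paralogs (Ly6, Slfn, Ifit, Oas, Gbp, Sprr2, Csf2rb2, H2 and Mup genes) may share reads, so which member changed is uncertain.

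RNA from other cells was followed by the share of UMIs from 19 endothelial markers, by hepatocyte transcripts, and by the level of each called gene relative to the class where it was highest. Alternatives were RLE normalization, DESeq2 1.42.0, limma-voom, no filter on low counts, the replicate number as a block, leaving out each mouse, sums thinned to the lowest total, hepatocyte transcripts left out, and other limits on doublets, genes, mitochondrial UMIs and Leiden resolution. Those chosen after seeing the data left out cells of other classes with over 0.5% of UMIs from endothelial markers, counted mixed clusters with their non-endothelial partner, or left out cluster 22 from the monocyte/macrophage class.

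The tests were run on simulated counts drawn to the depth and spread of each class, with 100 genes changed 2-fold and 100 changed 4-fold. At 4-fold, 95% were recovered in Kupffer, 94% in endothelial, 91% in monocyte/macrophage, 84% in stellate/fibroblast, 82% in plasmacytoid dendritic, 79% in conventional dendritic and 68% in T/NK cells. At 2-fold these were 64%, 54%, 45%, 28%, 32%, 20% and 21%, so many small changes are missed. False calls were 13 of 172, 4 of 152, 10 of 146, 20 of 132, 14 of 128, 4 of 103 and 2 of 91 in the same order, above the nominal share in several classes. For the differences between classes, 73.7% and 58.2% were recovered at 4-fold in the stellate/fibroblast and monocyte/macrophage tests, and 10.4% and 14.1% at 2-fold. A list of 50 genes raised 4-fold was called in each of the 7 classes. Whole libraries of the same group differed in their gene totals by far more than counting error (chi-square per degree of freedom 71.7 over 14905 genes in corn oil and 93.1 over 14956 in CCl4).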

Results

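Repeated dosing with carbon tetrachloride (CCl4), a solvent that injures hepatocytes and is used to produce liver fibrosis in mice, was compared with dosing with its vehicle, corn oil. The cells sequenced were the nonparenchymal cells of the liver, the fraction left after hepatocytes were spun down at 50 × g. It holds the sinusoidal endothelium, the stellate cells and fibroblasts that make scar matrix, the resident macrophages (Kupffer cells), recruited myeloid cells, lymphocytes and bile duct cells. Wild-type male mice aged 8 to 10 weeks received intraperitoneal injections 2 times a week for 5 weeks and were killed 48 hours after the last one. There were 4 single-cell libraries, 2 from corn oil mice and 2 from CCl4 mice, and the labels give 1 mouse per sample. The corn oil 1 library held 7167 cells and 50422053 UMIs (unique molecules counted), and corn oil 2 held 7663 cells and 51752732 UMIs. The CCl4 1 library held 6313 cells and 55529871 UMIs, and CCl4 2 held 5948 cells and 45408857 UMIs. Median UMIs per cell were 5397, 4493, 6861 and 6162 in corn oil 1, corn oil 2, CCl4 1 and CCl4 2, so the CCl4 cells were deeper.

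Clustering of the 24565 cells that passed the filters gave 35 clusters, of which 24 were named from marker genes. They formed 8 classes, called endothelial, stellate/fibroblast, Kupffer, monocyte/macrophage, conventional dendritic, plasmacytoid dendritic, T/NK and cholangiocyte for short. Each name means only that the cells resembled that type by its markers (endothelial-like, Kupffer-like and so on). The 11 unnamed clusters carried markers of different lineages together, most often endothelial ones with those of another cell type, and held 12.4% and 16.7% of the corn oil cells and 8.90% and 5.98% of the CCl4 cells. Several classes were held by different clusters in the 2 groups, and these are named beside the class. Expression is given as CPM, the summed UMIs of a class in each mouse scaled to a common library size, as mean ± SD over the 2 mice of a group. Changes are log2 fold changes of CCl4 over corn oil with their standard error (SE), tested with edgeR across mice, and intervals and lower bounds cover counting error only.

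The makeup of the nonparenchymal fraction addresses which cells accumulate during chronic injury. Monocyte- and macrophage-like cells made up a far larger part of the cells after CCl4, and endothelial cells a smaller part. The monocyte/macrophage class rose from 1.60% ± 0.476 of named cells in corn oil to 25.2% ± 7.52 in CCl4 (log2 3.98, SE 0.418, adjusted p = 0.0187). The class joins 2 clusters that moved differently, so this size depends on joining them: of all cells, cluster 0 went from 0.338% and 0.145% to 17.6% and 27.7%, and cluster 22 from 0.768% and 1.47% to 0.514% and 1.07%. Conventional dendritic cells, which present antigen to T cells, rose from 1.07% ± 0.40 to 4.11% ± 0.012 (log2 1.94, SE 0.344, adjusted p = 0.0351). The endothelial share fell from 82.3% ± 1.12 to 51.4% ± 2.52 (log2 -0.68, SE 0.13, adjusted p = 0.0351). T and NK cells fell from 4.12% ± 0.973 to 1.27% ± 0.407 (log2 -1.70, SE 0.363, adjusted p = 0.0357). The Kupffer share went from 5.63% ± 0.072 to 8.20% ± 0.262 (log2 0.54, SE 0.127, adjusted p = 0.0364). For these 5 classes both CCl4 mice lay on one side of both corn oil mice, and the exact two-sided permutation p was 0.333, the smallest that 2 against 2 mice can give. The stellate/fibroblast share was 10.4% in CCl4 1 but 3.45% in CCl4 2, against 3.28% and 2.88% in corn oil, and was not called (log2 1.17, SE 0.656, adjusted p = 0.230, exact permutation p = 0.333). Plasmacytoid dendritic cells (log2 0.51, adjusted p = 0.314, exact permutation p = 0.667) and cholangiocytes (log2 0.08, adjusted p = 0.944, exact permutation p = 1) were not called either.

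These are shares of recovered cells, so a rise in one class lowers the others, and the cells removed before sequencing are not in them. The Kupffer and endothelial calls depended on the unnamed clusters. With the cells of mixed clusters added to the non-endothelial partner, the Kupffer log2 ratio was -0.13 and the endothelial one -0.58, neither called, and with composition factors (TMM) on the cell numbers the Kupffer ratio was -0.38 and that of conventional dendritic cells 1.01, no longer called. The 2 clusters that carried Kupffer and endothelial markers together and were not cycling held 5.60% ± 1.68 of corn oil and 2.39% ± 1.74 of CCl4 cells. The cycling cluster 23, with both marker sets too, held 1.34% ± 0.021 and 0.34% ± 0.004 and was added to no class. For stellate with endothelial markers these shares were 2.60% ± 0.151 and 0.217% ± 0.064, so the low stellate share in corn oil leaves out many such cells. Leaving out any 1 mouse kept the direction of all 5 called shares, from log2 3.64 to 4.32 for monocyte/macrophage cells, 1.61 to 2.39 for conventional dendritic cells -2.07 to -1.41 for T/NK cells, 0.51 to 0.57 for Kupffer cells and -0.73 to -0.63 for endothelial cells. The stellate/fibroblast ratio, not called, ranged from 0.16 without CCl4 1 to 1.75 without CCl4 2, and that of plasmacytoid dendritic cells from 0.19 without corn oil 2 to 0.94 without corn oil 1. With no doublets removed the monocyte/macrophage ratio was 6.56, and with at most 15% mitochondrial UMIs the Kupffer ratio was 1.09, both called. With 3 mice each call was lost, except that of the conventional dendritic cells without corn oil 1.

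**Figure D1:**
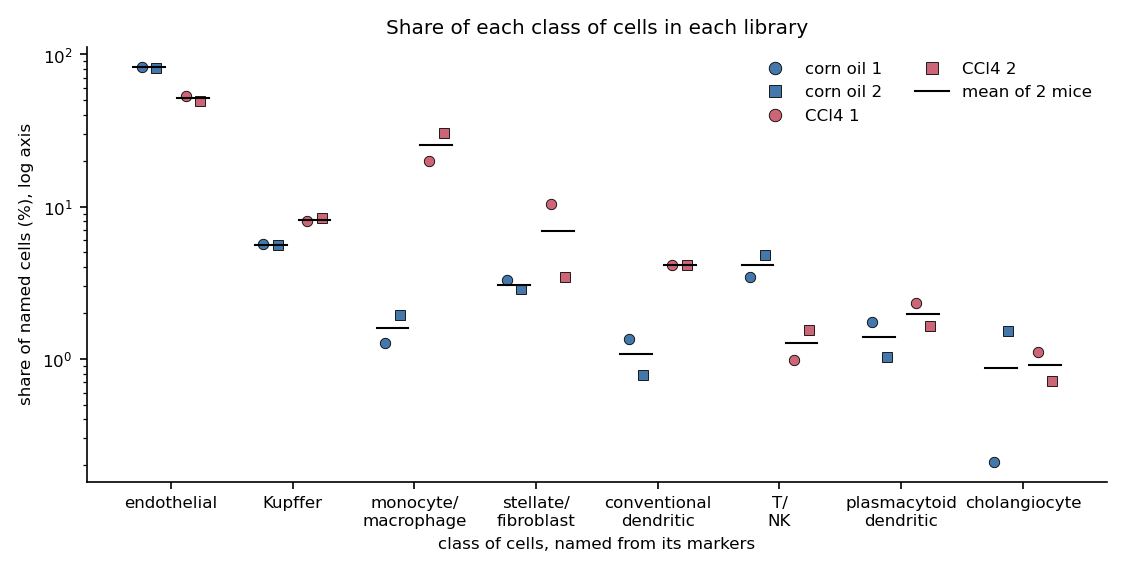
Share of named cells (percent, log axis) of each class in the 4 libraries, with 1 point per mouse and a bar at the mean of the 2 mice of a group. Monocyte/macrophage cells stood at 1.60% in corn oil and 25.2% in CCl4, while the stellate/fibroblast points of the CCl4 mice lay far apart at 10.4% and 3.45%.

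The stellate/fibroblast class holds the cells that turn into matrix-producing myofibroblasts in fibrosis, and the comparison asks what CCl4 changed in them. Contractile and matrix-remodelling genes were higher and those of quiescent, vitamin A-storing stellate cells lower. Fry called these lists, TGF-beta targets and basement membrane genes (adjusted p at most 0.0278). With an estimated correlation none was called (lowest adjusted p = 0.216). Of 9312 genes tested, 642 were higher and 665 lower in CCl4. Cluster 20 held 73.8% and 77.0% of the class in the corn oil mice, while cluster 13 held 77.9% and 54.3% in the CCl4 mice. The fibroblast-like cluster 21, led by Col1a1, Col1a2 and Mmp2, went from 14.97% and 15.76% of the class to 22.1% and 44.5%, so changes of the class hold this shift too. Timp1 (chromosome X, 20870166 to 20874735, GRCm38), which inhibits the proteases that degrade matrix, rose from 5.89 ± 4.78 to 239 ± 37.9 CPM (log2 5.26, SE 0.368, adjusted p = 4.6e-05). Thbs1, a matricellular protein that activates latent TGF-beta, rose from 46.6 ± 46.3 to 1347 ± 201 CPM (log2 4.81, SE 0.485, adjusted p = 0.000197). Serpina3n, a secreted protease inhibitor (chromosome 12, 104406729 to 104414329), rose from 25.5 ± 15.6 to 741 ± 201 CPM (log2 4.90, SE 0.358, adjusted p = 4.6e-05). The other genes among the 9 largest increases were Saa3, Ankrd1, Gpr176, Lcn2, Ch25h and Plaur. Ch25h, which makes 25-hydroxycholesterol, rose from 4.35 ± 2.59 to 180 ± 43.0 CPM (log2 5.31, adjusted p = 4.6e-05). Others of these were almost absent from corn oil cells. The acute-phase gene Saa3 had 993 UMIs in CCl4 against 1 in corn oil (ratio 289.8, 95% interval 51.9 to 11456), and the YAP target Ankrd1 had 770 against 1 (ratio 224.7, 40.2 to 8886).

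Among the stellate/fibroblast genes that fell were Ptprt, a receptor phosphatase with 150 UMIs in corn oil against 2 (ratio 257, 95% interval 69.9 to 2142), and the chemokine scavenger Ackr4 (82.4 ± 4.41 to 1.11 ± 1.26 CPM, log2 -6.82). Next came Clec4f, whose corn oil level was 1.25% of that in Kupffer cells, then Rassf4, Podn and the clock output gene Dbp (log2 -3.09). Ecm1, a secreted protein that restrains TGF-beta activation and is a major transcript of quiescent stellate cells, fell from 8006 ± 15.3 to 2405 ± 503 CPM (log2 -1.73, SE 0.215, adjusted p = 0.000561). Angptl6 fell from 591 ± 6.36 to 76.2 ± 25.8 CPM (log2 -2.92, adjusted p = 6.71e-05). Hhip, an inhibitor of hedgehog signalling, fell from 557 ± 100 to 154 ± 92.2 CPM (log2 -1.83, adjusted p = 0.00483), a call that DESeq2 did not make. The count of 1307 changed genes was 852 without corn oil 1, 753 without corn oil 2, 861 without CCl4 1 and 747 by DESeq2. Endothelial marker RNA in the class was 0.282% of UMIs in corn oil and 0.103% in CCl4, and 76 of the 665 lower genes stood in corn oil at under 10% of their level in another class, for 40 of them the endothelial class.

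Contractile genes of myofibroblasts rose as a set in stellate/fibroblast cells: 17 of 23 rose, 1 fell and 5 were not called (18 and 1 adjusted over the list alone), with a median log2 of 1.17 (camera adjusted p = 3.2e-14, adjusted p = 0.216 with an estimated correlation). Acta2, smooth muscle actin (chromosome 19, 34241090 to 34255590), rose from 115 ± 24.2 to 783 ± 82.5 CPM (log2 2.77, SE 0.216, adjusted p = 6.33e-05), Tagln from 275 ± 13.1 to 1656 ± 124 CPM (log2 2.59), and Tpm1 from 268 ± 36.8 to 1313 ± 81.3 CPM (log2 2.29), with Tagln among the genes that lead clusters 13 and 21. Of 27 genes of matrix cross-linking and turnover, 14 rose and 2 fell (14 and 3 adjusted over the list alone), with a median of 0.87 (camera adjusted p = 6.49e-06, adjusted p = 0.216 with an estimated correlation). They included the collagen cross-linker Lox (log2 3.34) and the metalloproteinase Mmp19 (log2 3.02). TGF-beta and YAP targets rose in 10 and fell in 2 of 26 (14 and 2 adjusted over the list alone; median 0.59, camera adjusted p = 0.000228, adjusted p = 0.216 with an estimated correlation). Quiescence genes fell in 18 and rose in 1 of 33 (22 and 2 adjusted over the list alone; median -0.87, camera adjusted p = 3.26e-12, adjusted p = 0.216 with an estimated correlation), Lhx2 among them (log2 -1.69). Fibrillar collagens and matrix proteins moved less evenly, with 11 of 31 higher and 4 lower (13 and 6 adjusted over the list alone) and a median of 0.22 (camera adjusted p = 0.0116, adjusted p = 0.327 with an estimated correlation). The largest of these increases were Tnc (28.1 ± 4.76 to 377 ± 155 CPM, log2 3.76), Col12a1 (log2 3.11), Mfap2 (log2 2.39, not called by limma-voom) and Col8a1 (log2 2.38). That median was 0.51 without corn oil 1, 0.52 without CCl4 1 and -0.16 without CCl4 2, where the list was no longer called.

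Basement membrane genes rose in 5 and fell in 0 of 16 in the stellate/fibroblast class (6 and 1 adjusted over the list alone; median 0.33, camera adjusted p = 0.0116, adjusted p = 0.237 with an estimated correlation). Col4a5 (log2 2.56), Col15a1 (log2 2.04), Col4a2 (log2 1.59) and Col4a1 (1129 ± 201 to 3366 ± 624 CPM, log2 1.58, adjusted p = 0.000959) led the list. Genes of the unfolded protein response and the secretory pathway, which expand when cells export much protein, rose in 15 of 27 and fell in 0 (19 and 0 adjusted over the list alone; median 0.73, camera adjusted p = 1.01e-11, adjusted p = 0.237 with an estimated correlation), and the median was 1.10 without corn oil 1. Inflammatory genes rose in 7 and fell in 2 of 24 (9 and 2 adjusted over the list alone; median 0.55, camera adjusted p = 0.0116, adjusted p = 0.431 with an estimated correlation). That median was 1.897 without corn oil 1, and the call was lost without corn oil 2 (0.35) or CCl4 1 (0.14). Immediate early and dissociation stress genes rose in 7 and fell in 2 of 40 (9 and 2 adjusted over the list alone; median 0.28, camera adjusted p = 0.00612, adjusted p = 0.603 with an estimated correlation). The metal-binding Mt2 led them, with a wide spread between mice (466 ± 18.4 to 2587 ± 1644 CPM, log2 2.47, and 1.62 without CCl4 1). The median of that list was 0.53 without corn oil 1, 0.54 without CCl4 2 and -0.14 without CCl4 1, where it was not called. The lists of interferon response, MHC class II, cell cycle, NRF2 response and hepatocyte transcripts were not called in this class (camera adjusted p from 0.062 to 0.351). With 1 mouse left out some were. Interferon genes were called upward without corn oil 1 (0.45) or CCl4 2 (0.29). MHC class II was called downward without corn oil 2 (-0.91) or CCl4 1 (-1.001). Cell cycle was called downward without corn oil 2 (-1.31). Hepatocyte transcripts were called upward without CCl4 1 (1.19) and downward without CCl4 2 (-0.72).

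Liver sinusoidal endothelial cells are fenestrated scavenger cells that lose their fenestrae and take on features of continuous capillaries in fibrosis. The endothelial class was the deepest, with 16260548 to 25026190 UMIs per mouse, and 627 of 12265 genes were higher and 438 lower after CCl4. Of sinusoidal identity genes 8 of 28 were lower, and of genes of capillarised endothelium 15 of 35 were higher. With an estimated correlation neither list was called (adjusted p = 0.513 for both). Hardly any cluster was shared: clusters 3 and 4 held 47.0% and 40.5% of corn oil 1, clusters 1 and 5 held 49.2% and 42.0% of corn oil 2, cluster 2 held 72.8% of CCl4 1 and cluster 6 held 72.4% of CCl4 2. The 10 largest increases were Ctsj, Sprr2b, Serpina3n, Tubb3, Csf2rb2, Adamts4, Steap2, Cfap69, Ch25h and Myc. Serpina3n rose from 3.19 ± 0.72 to 229 ± 20.8 CPM (log2 6.15, SE 0.214, adjusted p = 2.7e-05), so it rose in endothelial and stellate cells alike. The cysteine protease Ctsj rose from 0.16 ± 0.06 to 77.9 ± 32.9 CPM (log2 8.89, SE 0.464, adjusted p = 0.000103), and the cytokine receptor subunit Csf2rb2 from 3.89 ± 0.22 to 86.0 ± 17.1 CPM (log2 4.47). The growth regulator Myc rose from 12.5 ± 0.41 to 139 ± 71.2 CPM (log2 3.47, adjusted p = 0.00136). Hlf, a clock-driven transcription factor (chromosome 11, 90336536 to 90390895), fell the most, from 108 ± 42.6 to 2.0 ± 0.28 CPM (log2 -5.75, SE 0.33, adjusted p = 0.000155). It was followed by Ackr4 (log2 -3.65), Prelp, whose level was 4.49% of that in stellate cells, Gpr155 (log2 -2.79) and the Rac activator Tiam1 (log2 -2.51, and -2.05 without CCl4 1, not called there). Of the 627 higher genes, 149 stood in CCl4 at under 10% of their level in another class, 56 of them in monocyte/macrophage cells, which were more abundant in CCl4. The count of 1065 changed genes was 306 without CCl4 1, 505 without CCl4 2 and 2145 with no filter on low counts.

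Sinusoidal identity genes fell in 8 and rose in 1 of 28 in the endothelial class (16 and 2 adjusted over the list alone), with a median of -0.44 (camera adjusted p = 1.22e-05, adjusted p = 0.513 with an estimated correlation). Ehd3, an endocytic trafficking protein (chromosome 17, 73804134 to 73832094), fell from 5855 ± 686 to 1743 ± 179.9 CPM (log2 -1.75, SE 0.17, adjusted p = 0.00136), and the secreted nuclease Dnase1l3 from 6856 ± 509.9 to 3108 ± 96.5 CPM (log2 -1.14, adjusted p = 0.00502). The hyaluronan receptor Lyve1 went the other way, from 1010.4 ± 17.3 to 2171 ± 368 CPM (log2 1.10, SE 0.165, adjusted p = 0.0077). The VEGF receptor Kdr fell by 0.999 on the log2 scale but was not called without CCl4 1 (-1.08) or CCl4 2 (-0.94). Genes of capillarised and continuous endothelium rose in 15 and fell in 3 of 35 (18 and 4 adjusted over the list alone), with a median of 0.62 (camera adjusted p = 4.27e-06, adjusted p = 0.513 with an estimated correlation). The leukocyte adhesion molecule Sele rose from 7.88 ± 2.48 to 49.3 ± 28.0 CPM (log2 2.64) and the tip cell gene Esm1 from 24.3 ± 12.3 to 148 ± 4.92 CPM (log2 2.61, SE 0.311, adjusted p = 0.0029). Zonation lists were not called (central side 2 higher and 2 lower of 13, camera adjusted p = 0.880, portal side 3 and 1 of 18, camera adjusted p = 0.211), but the portal one was called upward without corn oil 2 (0.51). Lyve1 and Esm1 lead cluster 2, which held 72.8% of CCl4 1 and 8.59% of CCl4 2, and Dnase1l3 and Kdr lead clusters of the corn oil mice. Single zonated genes did change, the central adhesion molecule Cdh13 (249 ± 30.1 to 89.6 ± 29.7 CPM, log2 -1.47) among them. The signal Wnt2 (log2 -0.94) lost its call without CCl4 1 (-0.95) or CCl4 2 (-0.94).

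Matrix lists were not called in endothelial cells (fibrillar collagens and matrix proteins 6 higher and 2 lower of 24, basement membrane 4 and 1 of 14, camera adjusted p = 0.102 for both). The first of these was called upward without CCl4 1 (0.64, adjusted p = 0.0167). Within the basement membrane list Col18a1 rose from 0.75 ± 0.08 to 9.5 ± 0.49 CPM (log2 3.66, adjusted p = 0.000654), the laminin Lama3 fell (log2 -2.84), and Col4a2 (log2 1.20) and Col4a1 (691 ± 212 to 1349.8 ± 94.1 CPM, log2 0.97) lost their calls without CCl4 1 (1.07 and 0.88) or CCl4 2 (1.30 and 1.03). Inflammatory genes rose in 10 and fell in 1 of 31 (19 and 4 adjusted over the list alone; median 1.33, camera adjusted p = 2.84e-05, adjusted p = 0.513 with an estimated correlation). The members with the largest changes, Il1rn (5.18 ± 2.25 CPM in CCl4) and Lcn2 (5.79 ± 4.19 CPM), stood at 1.30% and 5.85% of their level in Kupffer and monocyte/macrophage cells. Unfolded protein response genes rose in 8 and fell in 0 of 30 (19 and 1 adjusted over the list alone; median 0.64, camera adjusted p = 3.21e-08, adjusted p = 0.513 with an estimated correlation), with the chaperone Hyou1 at log2 1.76. The NRF2 list, genes of the response to oxidants, was called upward (4 higher and 3 lower of 30, 8 and 4 adjusted over the list alone; median 0.32, camera adjusted p = 0.0201, adjusted p = 0.702 with an estimated correlation), but not without corn oil 2 (0.23) or CCl4 1 (0.23). Interferon genes were called upward by a small median of 0.13 (6 higher and 2 lower of 42, 7 and 2 adjusted over the list alone; camera adjusted p = 0.0301, adjusted p = 0.575 with an estimated correlation), but not without CCl4 1 (0.04). TGF-beta and YAP targets rose in 3 and fell in 0 of 24, also adjusted over the list alone (median 0.17, camera adjusted p = 0.0299, adjusted p = 0.513 with an estimated correlation). That median was 0.40 without corn oil 2 and 0.31 without CCl4 2, and the list was not called without corn oil 1 (0.19) or CCl4 1 (0.11). Immediate early genes were called downward (1 higher and 5 lower of 41, 1 and 7 adjusted over the list alone; median -0.16, camera adjusted p = 0.0174, adjusted p = 0.821 with an estimated correlation). The median was -0.81 without CCl4 1, -0.38 without corn oil 2 and 0.01 without CCl4 2, and the call was lost without corn oil 1 (-0.16) or with the replicate number as a block (-0.25). MHC class II, cell cycle and hepatocyte lists were not called (camera adjusted p from 0.211 to 0.617). Hepatocyte transcripts were called upward without CCl4 1 (0.59) and downward without CCl4 2 (-0.68).

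Whether stellate and endothelial cells responded differently was tested directly, with each mouse as a block. The CCl4 effect differed in 708 of 13095 genes, 270 with a higher and 438 with a lower effect in stellate/fibroblast cells. Tpm1, Thbs1, Lox and Col8a1 rose more in stellate cells: the difference in log2 effect was 1.82 for Tpm1 (SE 0.174, adjusted p = 3.47e-05), 2.28 for Thbs1 (adjusted p = 0.00303), 1.93 for Lox (adjusted p = 0.00267) and 2.16 for Col8a1 (adjusted p = 0.00384). The stress gene Mt2 also rose more there (2.16, SE 0.188, adjusted p = 1.83e-05). Endothelial cells had the larger increase in Myc (-2.67, adjusted p = 0.000673) and Col18a1 (-2.61, adjusted p = 0.00521). Hlf fell less in stellate cells (2.89, adjusted p = 0.000257), and Gas6, a ligand of TAM receptors, fell in endothelial cells with a difference of 1.66 (adjusted p = 0.00588). No difference was shown for Col4a1 (0.57, adjusted p = 0.111), Hspa5 (-0.16, adjusted p = 0.84), Timp1 (1.20, adjusted p = 0.171), Acta2 (1.07, adjusted p = 0.118), Tagln (0.91, adjusted p = 0.132), Col1a1 (-0.83, adjusted p = 0.0939) or Serpina3n (-1.26, adjusted p = 0.0817). Tnc is not compared, since endothelial cells held 27 UMIs of it in CCl4 against 1 in corn oil. The Acta2 effect in endothelial cells (log2 1.72) concerns a gene at 783 CPM in stellate cells after CCl4 and at most 15.4 CPM in any other tested class. Without corn oil 1 the count was 383.

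Kupffer cells are the resident macrophages of the sinusoids, and the comparison asks how far CCl4 moved them from that identity. Genes of lipid- and scar-associated macrophages rose while Kupffer identity and antigen presentation genes fell. Fry called only the first 2 lists (adjusted p = 0.02115) and an estimated correlation none (adjusted p = 0.182, 0.182 and 0.476). Of 10537 genes tested, 1479 were higher and 1458 lower. Cluster 9 held 77.8% and 85.0% of the class in corn oil, and cluster 11, led by Mmp12 and Mmp13, 69.0% and 70.6% in CCl4. Clec4f, Vsig4, Cd5l, Folr2 and Marco lead both. Cluster 27, led by Cd207, fell from 21.3% and 14.4% to 5.16% and 5.23%, so changes of the class hold this shift too. The largest increases, in order, were Adam8, Mmp12, Gpnmb, Spp1, Il7r, Thbs1 and Fabp5. The macrophage elastase Mmp12 (chromosome 9, 7344381 to 7369499) rose from 11.5 ± 4.85 to 1619.5 ± 455 CPM (log2 7.15, SE 0.321, adjusted p = 1.42e-05) and the lysosomal glycoprotein Gpnmb from 13.7 ± 11.9 to 1301 ± 134 CPM (log2 6.62, SE 0.435, adjusted p = 4.29e-05). Adam8, a membrane protease, rose from 4.37 ± 4.41 to 664 ± 52.6 CPM (log2 7.32), and osteopontin, Spp1, from 6.17 ± 6.09 to 403 ± 123 CPM (log2 6.09). Thbs1 stood at 2.78% of its level in monocyte/macrophage cells. Among the genes that fell were the prostacyclin synthase Ptgis (log2 -4.43), the clock repressor Nr1d1 (88.1 ± 45.7 to 5.77 ± 0.53 CPM, log2 -3.93) and the stellate matrix genes Reln and Dcn. Dcn (625 ± 126 to 45.8 ± 22.5 CPM) stood at 4.11% of its stellate level. In all, 336 of the 1458 lower genes (23.1%) were at under 10% of another class in corn oil, 185 of them in stellate cells, and endothelial marker RNA in Kupffer cells was 0.107% of UMIs in corn oil and 0.0402% in CCl4. The count of 2937 changed genes was 1716 without CCl4 1, 1829 without CCl4 2 and 1821 by DESeq2.

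Lipid- and scar-associated genes rose in 27 and fell in 1 of 33 in Kupffer cells (28 and 2 adjusted over the list alone), with a median log2 of 2.13 (camera adjusted p = 1.28e-16, adjusted p = 0.182 with an estimated correlation). Kupffer identity genes fell in 19 and rose in 1 of 27 (20 and 1 adjusted over the list alone), with a median of -0.77 (camera adjusted p = 5.7e-10, adjusted p = 0.182 with an estimated correlation). The 1 that rose was the scavenger receptor Marco (662 ± 56.3 to 4072 ± 704 CPM, log2 2.62, SE 0.182, adjusted p = 4.62e-05). The lectin Clec4f (chromosome 6, 83644542 to 83656187) fell from 4864 ± 339 to 1429.6 ± 173 CPM (log2 -1.77, SE 0.168, adjusted p = 0.000204), complement C6 from 1582 ± 326 to 399.6 ± 35.6 CPM (log2 -1.99) and the prostaglandin-degrading enzyme Hpgd from 1223 ± 73.9 to 300.5 ± 62.7 CPM (log2 -2.02). MHC class II presentation genes fell in 9 and rose in 0 of 13 (11 and 0 adjusted over the list alone; median -0.998, camera adjusted p = 4.04e-05, adjusted p = 0.476 with an estimated correlation). The transactivator Ciita (log2 -1.83) and H2-DMa (log2 -1.28) fell, and H2-Ab1 fell from 2236 ± 843 to 944 ± 62.2 CPM (log2 -1.24, and -0.81 without corn oil 2). Genes of monocyte-derived cells rose in 11 and fell in 2 of 26 (12 and 2 adjusted over the list alone; median 0.60, camera adjusted p = 0.00156, adjusted p = 0.476 with an estimated correlation). Chil3 (114 UMIs in CCl4 against 1, ratio 66.7, 95% interval 11.7 to 2658) stood at 0.67% of its monocyte/macrophage level, and the integrin Itgam rose from 63.0 ± 4.91 to 331 ± 1.12 CPM (log2 2.39).

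Cell cycle genes rose in 15 and fell in 1 of 32 in Kupffer cells (17 and 2 adjusted over the list alone; median 0.90, camera adjusted p = 0.000165, adjusted p = 0.491 with an estimated correlation), the helicase-like Hells (log2 3.03), Uhrf1 (log2 3.02) and the replication licensing gene Mcm5 (11.8 ± 2.34 to 80.9 ± 35.3 CPM, log2 2.77) among them. The cycling cluster 23, with Kupffer and endothelial markers, lies outside the class. It held 1.35% and 1.32% of corn oil cells against 0.343% and 0.337% of CCl4 cells, so how far this list rose in Kupffer cells stays open. Unfolded protein response genes rose in 20 and fell in 0 of 27 (21 and 0 adjusted over the list alone; median 0.78, camera adjusted p = 6.94e-09, adjusted p = 0.476 with an estimated correlation). Inflammatory genes rose in 16 and fell in 6 of 35 (16 and 8 adjusted over the list alone; median 0.57, camera adjusted p = 0.0154, adjusted p = 0.639 with an estimated correlation), but were not called as a set without CCl4 1 (0.23). The interleukin 1 antagonist Il1rn rose from 19.0 ± 9.17 to 398 ± 106 CPM (log2 4.41) and the chemokine Ccl9 from 55.8 ± 21.1 to 917 ± 154 CPM (log2 4.05). Immediate early and dissociation stress genes fell in 25 and rose in 5 of 41 (27 and 7 adjusted over the list alone; median -0.81, camera adjusted p = 1.85e-05, adjusted p = 0.563 with an estimated correlation). The condition of the cells differed too. The median mitochondrial share of Kupffer cells was 9.45% and 14.6% in corn oil and 7.38% and 8.77% in CCl4. Their median UMIs were 8303 and 7941.5 against 11188.5 and 12591. Hepatocyte transcripts fell in 11 and rose in 0 of 35, also adjusted over the list alone (median -0.60, camera adjusted p = 0.0148, adjusted p = 0.646 with an estimated correlation), and made up 0.267% of Kupffer UMIs in corn oil and 0.153% in CCl4. Their median was -0.97 without corn oil 1 and -1.10 without CCl4 2, and the call was lost without corn oil 2 (0.19) or CCl4 1 (-0.13). The interferon and NRF2 lists were not called (camera adjusted p = 0.579 and 0.361), though the interferon list was called downward without CCl4 1 (-0.31).

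**Figure D2:**
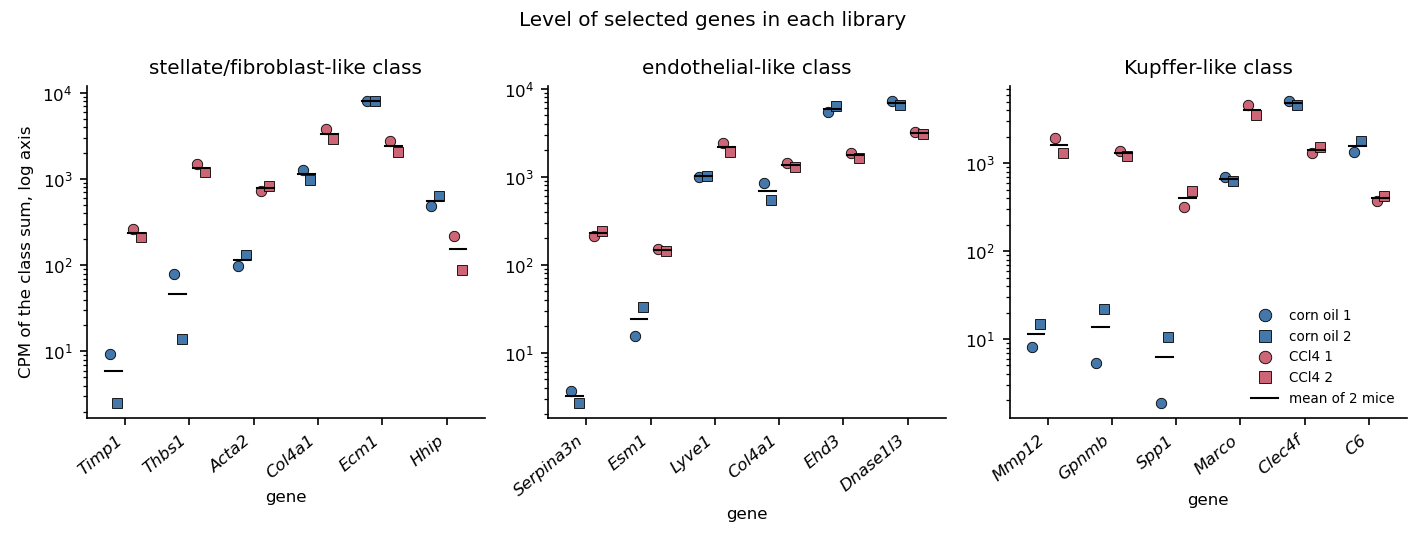
CPM (log axis) per mouse of 6 genes in each of the stellate/fibroblast, endothelial and Kupffer classes, with points for the 2 corn oil and the 2 CCl4 mice. Timp1 in stellate cells (5.89 to 239 CPM) and Mmp12 in Kupffer cells (11.5 to 1619.5 CPM) rose, while Ecm1, Ehd3 and Clec4f fell in their classes.

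The monocyte/macrophage class holds cells with monocyte and macrophage markers, which were few in corn oil livers, so its comparison sets few corn oil cells (72 and 111) against many CCl4 cells (1059 and 1534). The cells also differed in kind. Cluster 22, led by Arg1, Slpi, Saa3, Prg4 and Fn1, held 69.4% and 91.0% of the class in corn oil, and cluster 0, led by Chil3, F13a1 and Vcan, held 97.2% and 96.3% in CCl4. Of 10241 genes tested, 810 were higher and 1234 lower. Without cluster 22, which left 22 and 10 corn oil cells, 46 genes were called, 18 higher and 28 lower. The largest increases were Lcn2, Ptgs2, Ly6i, Ifi206, Ly6c2, Vcan, Slfn1, Ifit1, Rsad2 and Ifi27l2a. Ly6c2, the marker of inflammatory monocytes (chromosome 15, 75108158 to 75111970), rose from 31.0 ± 31.4 to 628 ± 164 CPM (log2 4.56, SE 0.55, adjusted p = 0.0012), and the antiviral effector Rsad2 from 7.87 ± 6.36 to 124 ± 23.0 CPM (log2 4.21). In corn oil, Ptgs2 UMIs came from corn oil 2 alone (log2 4.95) and Ifi206 UMIs from corn oil 1 alone (log2 4.63). Without the mouse that held them each ratio has no limit. The largest decreases were Alox15, Retnla, Mmp12, Cd5l, Plxdc2, Fgfr1, Prg4, Mgl2, Efnb2 and Gata6. Mmp12 fell from 1208 ± 2.49 to 22.9 ± 12.5 CPM (log2 -5.74, SE 0.36, adjusted p = 0.000118), and the transcription factor Gata6 from 76.2 ± 13.3 to 2.93 ± 0.62 CPM (log2 -4.73). Without cluster 22, corn oil held 1 UMI each of Mmp12 and Cd5l, so their fall was no longer seen and no direction is given, and of the genes named here only Vcan (2.998) and Mgl2 (-4.99) were still called. Of the named calls of the class, 39 had a value there, of which 30 lost the call and 7 turned, some of these on 0 to 2 corn oil UMIs. Endothelial marker RNA was 0.198% of UMIs in corn oil and 0.0238% in CCl4, and median UMIs per cell were 11884 and 5426. Of the 1234 lower genes, 253 were at under 10% of another class, 173 of them in endothelial cells. The count of 2044 was 1288 without corn oil 2, 1262 without CCl4 1 and 1278 without CCl4 2.

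Interferon response genes were the most uniform set in the monocyte/macrophage class, higher in CCl4 in 39 and lower in 0 of 44 (40 and 0 adjusted over the list alone), with a median of 2.49 (camera adjusted p = 2.38e-26, adjusted p = 0.13 with an estimated correlation). Their median was 1.45 without cluster 22, where camera still called the list but only 1 of 44 genes was called. The RNA sensor Oas3 had 783 UMIs in CCl4 against 1 in corn oil (ratio 126.9, 95% interval 22.7 to 5017) and Oas2 had 502 against 2 (ratio 40.7, 11.2 to 336.7). Genes of monocyte-derived cells rose in 14 and fell in 4 of 28 (16 and 4 adjusted over the list alone; median 0.86, camera adjusted p = 0.000275, adjusted p = 0.424 with an estimated correlation), and stood at 0.36 without cluster 22, still called by camera with 3 of 28 genes higher. Lipid- and scar-associated genes fell in 24 and rose in 1 of 33 (27 and 1 adjusted over the list alone; median -1.30, camera adjusted p = 3.06e-16, adjusted p = 0.13 with an estimated correlation), but turned to 0.49 without cluster 22. Kupffer identity genes fell in 15 and rose in 5 of 24, also adjusted over the list alone (median -1.64, camera adjusted p = 0.000285, adjusted p = 0.134 with an estimated correlation), turned to 0.70 without cluster 22, and stood at -1.06 with endothelial-carrying cells left out. Cell cycle genes fell in 29 and rose in 1 of 44 (36 and 2 adjusted over the list alone; median -2.33, camera adjusted p = 9.57e-14, adjusted p = 0.13 with an estimated correlation), and were not called without cluster 22 (0.22). Matrix cross-linking genes fell in 11 and rose in 1 of 18, also adjusted over the list alone (median -1.75, camera adjusted p = 1.62e-06, adjusted p = 0.13 with an estimated correlation), with -0.87 without corn oil 1 and -0.18 without cluster 22. NRF2 genes fell in 9 and rose in 2 of 30 (13 and 3 adjusted over the list alone; median -0.50, camera adjusted p = 0.00896, adjusted p = 0.287 with an estimated correlation), and turned to 0.66. The TGF-beta, inflammatory, MHC class II, immediate early, unfolded protein and hepatocyte lists were not called (camera adjusted p from 0.449 to 0.974). Of these, camera called 3 without cluster 22: MHC class II downward (0 higher and 4 lower of 12, median -0.94, adjusted p = 0.00587), inflammatory genes upward (3 and 1 of 31, median 0.49, adjusted p = 0.00587) and unfolded protein genes upward (0 and 0 of 27, median 0.36, adjusted p = 0.0394). With 1 mouse left out, unfolded protein genes were called downward without CCl4 1 (-0.23) and upward without CCl4 2 (0.17). Hepatocyte transcripts were called upward without CCl4 1 (1.10) and downward without CCl4 2 (-0.64). Immediate early genes were called upward without CCl4 2 (0.21).

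Between Kupffer and monocyte/macrophage cells the direct test found a different CCl4 effect in 3228 of 11192 genes. The effect was higher in monocyte/macrophage cells in 1468 and lower in 1760. Mmp12 rose in Kupffer cells and fell in the other class (difference -12.93, SE 0.292, adjusted p = 1.73e-10). Marco (-6.31, adjusted p = 2.84e-09), Adam8 (-8.35, adjusted p = 6.66e-09) and Gpnmb (-8.60, adjusted p = 6.22e-08) also rose in Kupffer cells and not in the other class. The interferon gene Ifi27l2a rose in monocyte/macrophage cells with a difference of 4.43 (SE 0.209, adjusted p = 5.66e-08), and Rsad2 with one of 4.13 (adjusted p = 5.67e-05). The clock gene Nr1d1 fell in both, with no difference shown (0.16, adjusted p = 0.779). In the monocyte/macrophage class the fall of Mmp12 came with cluster 22. Without cluster 22 the count was 449 (258 higher and 191 lower), and it was 1897 without corn oil 2 and 1994 without CCl4 1.

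Conventional dendritic cells take up and present antigen, and CCl4 changed 306 of their 7405 tested genes, 150 higher and 156 lower. Cluster 16 held most of the class in every mouse, and cluster 28, led by Ccl22 and Ccr7, rose from 1.30% and 4.44% of it in corn oil to 30.1% and 16.0% in CCl4. Ccl22, Lad1, Mmp25 and H2-Eb2 are among the genes that lead cluster 28. The 4 largest increases were Cxcl2 (257 UMIs in CCl4 against 1, ratio 74.2, 95% interval 13.2 to 2942, at 6.16% of its monocyte/macrophage level), Lad1 (312 against 2, ratio 45.0, 12.4 to 373.6), the lysosomal tetraspanin Cd63 and the protease Mmp25 (log2 4.66). Its corn oil UMIs came from corn oil 2 alone, without which the ratio has no limit. Cd63 rose from 10.9 ± 8.97 to 361 ± 143 CPM (log2 5.30, SE 0.5, adjusted p = 0.000528). Cyp8b1 (log2 -4.22) and Pianp (log2 -3.44) fell the most beside the endothelial transcript Cavin2 and the stellate transcript Bgn, which stood at 3.99% and 1.60% of their level in those classes, and Bgn (log2 -3.60) was not called without corn oil 1 (-2.88). The chemokine Ccl22 rose from 70.2 ± 28.6 to 486 ± 367 CPM (log2 2.88, and 1.79 without CCl4 1), a call not made by DESeq2 or limma-voom. MHC class II genes changed both ways, with 3 higher and 2 lower of 15 (4 and 7 adjusted over the list alone). Their median (-0.44) and test (camera adjusted p = 0.00299, adjusted p = 0.820 with an estimated correlation) were downward while their mean was 0.04, and the list was not called without corn oil 1 (-0.27). H2-Eb2 rose (11.1 ± 3.55 to 111 ± 52.1 CPM, log2 3.22, not called by limma-voom) and H2-Ob (chromosome 17, 34238903 to 34254414), which restrains peptide loading, fell from 266 ± 28.8 to 63.4 ± 5.63 CPM (log2 -2.08, SE 0.224, adjusted p = 0.000987). H2-Ob is among the genes that lead cluster 16.

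Interferon genes in conventional dendritic cells were called upward (2 higher and 0 lower of 42, 5 and 0 adjusted over the list alone; median 0.38, camera adjusted p = 0.000418, adjusted p = 0.820 with an estimated correlation), with a median of 1.24 without corn oil 1 and no call without corn oil 2 (0.05). NRF2 genes were called upward (3 higher and 0 lower of 21, 4 and 1 adjusted over the list alone; median 0.35, camera adjusted p = 0.00668, adjusted p = 0.679 with an estimated correlation), led by the glutathione synthesis gene Gclc (30.9 ± 5.09 to 201 ± 63.7 CPM, log2 2.74). Immediate early genes were called downward (1 higher and 5 lower of 40, 2 and 10 adjusted over the list alone; median -0.09, camera adjusted p = 0.00826, adjusted p = 0.828 with an estimated correlation), with Egr1 at log2 -1.53. That median was -0.32 without corn oil 2 and -0.46 without CCl4 1. The call was lost without corn oil 1 (-0.15) or with the replicate number as a block (-0.10), and the test turned upward without CCl4 2 (median -0.0061). The inflammatory, cell cycle, unfolded protein and hepatocyte lists were not called (camera adjusted p from 0.461 to 0.711). Inflammatory genes were called upward with the replicate number as a block (0.39) and without CCl4 2 (0.65). Hepatocyte transcripts were called upward without CCl4 1 (0.80) and downward without CCl4 2 (-1.24). The count of 306 was 172 by DESeq2 and 589 with no filter on low counts.

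Plasmacytoid dendritic cells, the main producers of type I interferon, changed least, with 2 genes higher and 29 lower of 5617. The edgeR calls were lost without CCl4 2, but the named genes kept their direction there. Without corn oil 1, corn oil 2 and CCl4 1 the counts were 59, 117 and 54, and with all mice DESeq2 called 16 and limma-voom 25. Of the 29 lower genes, 18 (62.1%) stood in corn oil at under 10% of another class, 16 of them in endothelial cells, the named Tinagl1, Flt1 and Stab2 among them, and with cells carrying endothelial RNA left out 13 genes were called. Endothelial marker RNA was 0.143% of UMIs in corn oil and 0.0203% in CCl4. The chemokine gene Ccl4, which only shares its letters with the toxin, fell from 1216 ± 108 to 306 ± 32.1 CPM (log2 -1.99, SE 0.176, adjusted p = 0.00017). H2-Ab1 fell from 2008 ± 377 to 933 ± 204 CPM (log2 -1.09) and H2-Aa by 1.03 on that scale. The 2 higher genes were Mir142hg (log2 1.39) and the interferon-induced Slfn5 (116 ± 37.8 to 311 ± 11.1 CPM, log2 1.35). Without CCl4 2, where no call was left, Ccl4 was at -2.08, H2-Ab1 at -0.875, H2-Aa at -0.80, Mir142hg at 1.28 and Slfn5 at 1.41, and Mir142hg was also not called without corn oil 1 (1.32). By camera the MHC class II list was called downward (0 higher and 2 lower of 10, 0 and 6 adjusted over the list alone; median -0.89, camera adjusted p = 7.02e-11, adjusted p = 0.279 with an estimated correlation). The interferon list was called upward (1 and 0 of 22, 8 and 0 adjusted over the list alone; median 0.46, camera adjusted p = 1.31e-09, adjusted p = 0.279 with an estimated correlation), with 1.06 without corn oil 1. The immediate early list was called downward (0 and 1 of 31, 0 and 6 adjusted over the list alone; median -0.39, camera adjusted p = 2.26e-06, adjusted p = 0.279 with an estimated correlation), with -0.67 without CCl4 1 and no call without corn oil 1 (-0.13), without CCl4 2 (-0.22) or with endothelial-carrying cells left out (-0.23). The other 5 lists were not called (camera adjusted p from 0.0686 to 0.772). Of these, inflammatory genes were called downward with the replicate number as a block (-0.21) and, with medians of 0.20 and 0.0034, without corn oil 1 or CCl4 1. Hepatocyte transcripts were called downward with the block (-0.37) and without corn oil 1 (-1.61). Cell cycle was called downward without CCl4 1 (-0.49), and unfolded protein genes upward without corn oil 1 (0.33) or CCl4 2 (0.21).

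T and NK cells were 1 class, few in CCl4 (52 and 78 cells, against 196 and 276). A shift between cell kinds in it cannot be told from change within cells. Of 6615 genes, 103 rose (Pdcd1, Foxp3 and Tnfrsf9 among them) and 113 fell (with Cxcr6). The inhibitory receptor Pdcd1 (chromosome 1, 94038305 to 94052553) rose from 4.70 ± 4.79 to 69.0 ± 2.55 CPM (log2 3.90, SE 0.587, adjusted p = 0.000677), the regulatory T cell factor Foxp3 from 11.5 ± 8.88 to 117 ± 86.8 CPM (log2 3.35, adjusted p = 0.00134) and the costimulatory receptor Tnfrsf9 from 22.9 ± 15.7 to 141 ± 46.5 CPM (log2 2.67). Their list, led by Rgs16 (26 UMIs in CCl4 against 3, ratio 18.2, 95% interval 5.6 to 94, not called without corn oil 1), was higher in 6 and lower in 0 of 16 (8 and 1 adjusted over the list alone; median 0.67, camera adjusted p = 6.15e-06, adjusted p = 0.414 with an estimated correlation), with 1.10 without corn oil 1. Cytotoxic and effector genes fell in 5 and rose in 1 of 26 (9 and 2 adjusted over the list alone; median -0.41, camera adjusted p = 0.0021, adjusted p = 0.442 with an estimated correlation), with -0.15 without CCl4 1 and no call without corn oil 1 (-0.21). The tissue-residency receptor Cxcr6 fell from 498 ± 57.3 to 163 ± 12.7 CPM (log2 -1.61, SE 0.206, adjusted p = 0.000149). Fasl (log2 -1.11) lost its call without corn oil 2 (-0.925), and the granzyme Gzma (1504 ± 125 to 872 ± 140.2 CPM, log2 -0.79) and Cd8b1 (log2 1.03) lost theirs without corn oil 1 (-0.71 and 0.68). The 4 largest increases were Il1b, Slfn4, Ccl1 and Spp1. Il1b and Slfn4 had no UMI in corn oil and were at least 33.6-fold and at least 32.2-fold higher (a floor of 3 UMIs over the group), but stood at 11.7% and 47.5% of their level in monocyte/macrophage cells. The chemokine Ccl1 had 152 UMIs against 1 (ratio 319.5, 95% interval 56.5 to 12702) and was not called by limma-voom. Atp8a2 (103 UMIs in corn oil against 2, ratio 24.5, 6.6 to 205) fell the most.

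Further lists were called in T/NK cells. Unfolded protein response genes rose in 2 and fell in 0 of 26 (8 and 0 adjusted over the list alone; median 0.51, camera adjusted p = 1.35e-06, adjusted p = 0.414 with an estimated correlation), with 0.26 without corn oil 2 and 0.26 without CCl4 2. The MHC class II list was called upward (1 higher and 0 lower of 6, 2 and 0 adjusted over the list alone; median 0.70, camera adjusted p = 0.0021, adjusted p = 0.414 with an estimated correlation), and its 1 called member, Ctss, stood at 5.31% of its monocyte/macrophage level. Inflammatory genes rose in 4 and fell in 0 of 14 (5 and 2 adjusted over the list alone; median 0.59, camera adjusted p = 0.00324, adjusted p = 0.414 with an estimated correlation). Their median was 0.25 without CCl4 2, and the call was lost without corn oil 1 (0.65) or corn oil 2 (1.09). Interferon genes rose in 2 and fell in 0 of 34 (4 and 0 adjusted over the list alone; median 0.27, camera adjusted p = 0.00451, adjusted p = 0.414 with an estimated correlation), with 0.49 without CCl4 2 and no call without corn oil 2 (0.51) or CCl4 1 (0.31). Of 40 cell cycle genes 0 were called, also adjusted over the list alone, while the set was called upward (median 0.90, camera adjusted p = 0.0187, adjusted p = 0.722 with an estimated correlation). It reached 1.76 without CCl4 2, and the test turned downward without CCl4 1 (-0.96) and without corn oil 2 (0.62). The cycling cluster 33 held 19.2% of the class in CCl4 1 and 0% in CCl4 2, and the cause of the turn was not tested. The call was also lost with endothelial-carrying cells left out (0.885, adjusted p = 0.068). The naive and central memory, immediate early, NRF2 and hepatocyte lists were not called (camera adjusted p from 0.0679 to 0.598). The naive list was called downward with the replicate number as a block (-0.22), without corn oil 1 (-0.53) and without CCl4 2 (-0.45). Hepatocyte transcripts were called upward without CCl4 1 (0.91) and downward without CCl4 2 (-2.17). NRF2 genes were called upward without corn oil 1 (0.35) and immediate early genes downward without CCl4 1 (-0.36). The count of 216 changed genes was 127 without corn oil 1, 130 without corn oil 2, 433 without CCl4 2, 54 by DESeq2, 76 with sums thinned to the lowest total and 102 with 10% of cells removed as doublets.

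**Figure D3:**
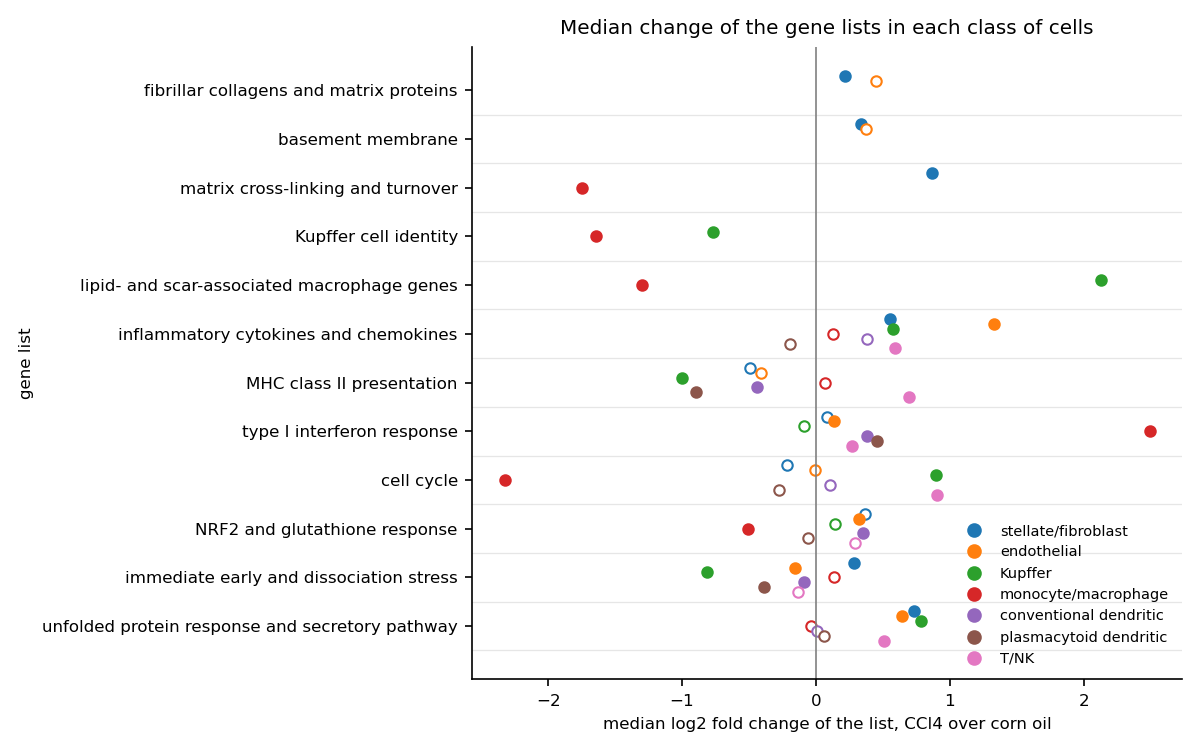
Median log2 fold change (CCl4 over corn oil) of selected gene lists in each class where they were tested. Points are filled where the camera adjusted p was under 0.05 and open where it was not. The interferon list in monocyte/macrophage cells (2.49) and the lipid- and scar-associated list in Kupffer cells (2.13) lay highest, and the cell cycle list in monocyte/macrophage cells (-2.33) lowest.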

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

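The tests of the first pattern below that leave out cluster 22, all tests of mixed cells and all tests of clock genes were chosen after the results had been seen, while the peritoneal gene list was written before its values were read. Results that differed between classes were the 708 genes with a different CCl4 effect in stellate/fibroblast and endothelial cells and the 3228 in monocyte/macrophage and Kupffer cells. Between the latter classes Mmp12 (difference -12.93), Mt2 (-3.53) and Srxn1 (-2.74) moved in opposite directions. Without cluster 22 corn oil held 1 UMI of Mmp12 and 2 of Srxn1, so their fall in monocyte/macrophage cells was no longer seen, and Mt2 lost its call there (-0.83). A cluster with neutrophil and endothelial markers held a mean of 0.614% of cells in CCl4 and 0.045% in corn oil. It stayed unnamed and neutrophils were not analysed as a class.

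The corn oil monocyte/macrophage cells lay mainly in cluster 22, which held few CCl4 cells. The called genes had a median log2 change of 1.25 in the direction of their call, and 0.409 without that cluster, over 1714 of the 2044 genes, so the calls come in large part from different kinds of cells in the 2 groups. Of 10 further genes of peritoneal macrophages, 9 were highest in cluster 22 among the named myeloid clusters (Aspa was not), so the cluster may hold macrophages from the peritoneal cavity. How they came into the samples was not tested.

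Clusters with Kupffer and endothelial markers held 47.0% and 59.3% of their cells and the named Kupffer cells together in corn oil, and 33.1% and 12.8% in CCl4. The cycling cluster and the one with Kupffer and stellate markers are left out of this. Free endothelial RNA and random capture of 2 cells together would reach every cell type alike. Both were argued against by the T/NK class, where such cells were rarer by at least 3.18 times (21.04 in the other corn oil library). Cell by cell, with over 0.5% endothelial UMIs as the mark, the corn oil shares were 50.1% and 62.3% of Kupffer, 18.3% and 8.80% of T/NK, 3.90% and 6.67% of conventional dendritic and 5.05% and 3.39% of plasmacytoid dendritic cells. Types found only in mixed clusters had more than T/NK cells: 40.7% and 21.1% of B, 40.4% and 66.1% of mesothelial and 100% of the few neutrophils. Median endothelial marker UMIs per cell were 61 and 197 in Kupffer and 1 and 1 in T/NK cells. By cluster, stellate-marked cells were mixed in 46.4% and 53.0% in corn oil and 1.78% and 7.49% in CCl4. A further candidate explanation, also left open, is incomplete separation of cells that touch in the sinusoid, more often in corn oil livers. It was not tested, and whether it would reach B cells and neutrophils is not known.

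Clock output genes were called lower in 7 of 9 in endothelial, 5 of 8 in stellate/fibroblast, 7 of 9 in Kupffer, 5 of 8 in monocyte/macrophage and 2 of 4 in T/NK cells. Of genes of the opposite phase, Arntl (2.19) and Nfil3 (2.96) were called higher in endothelial cells and Nfil3 in stellate/fibroblast (3.63) and Kupffer cells (4.11), while Clock and Cry1 were called in no class. RNA from other cells was argued against as the source of the set. In endothelial cells the median of the output genes, relative to the other class where each was highest, stood 296.22 times above that of abundant stellate markers. Against the markers of other classes it stood at least 5.15 times higher in monocyte/macrophage, 13.19 times in Kupffer and 20.76 times in stellate/fibroblast cells. Single genes stay open: Hlf in Kupffer cells stood at 0.0258 of its stellate level, near the stellate markers (0.0213). Death at different times of day stays open: the corn oil mice differed from each other in Nr1d1, with a median log2 ratio of 1.104 over classes, and in Cry1 by -1.76 in endothelial, -2.38 in stellate/fibroblast and -3.52 in Kupffer cells. Of the CCl4 mice, the first was also higher in Nr1d1 in all 5 classes with values (0.174 to 1.686) and lower in Cry1 in endothelial (-0.438), stellate/fibroblast (-0.081) and Kupffer cells (-0.99). Cry1 did not follow this in conventional dendritic cells (0.647), nor in CCl4 monocyte/macrophage cells (0.379). An effect of CCl4 on the clock at 1 time of day was not tested and stays open too.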

How the results depend on the processing

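The settings that leave out cluster 22, leave out endothelial-carrying cells or count mixed clusters were chosen after the results had been seen. Sensitivity is given here for lists and genes called with all data, and the report names the other lists that a setting called. RLE normalization kept all 328 named calls and moved no class median by more than 0.0114. DESeq2 lost 36 named calls and limma-voom 28. With DESeq2 the genes called were 1821 in Kupffer, 747 in stellate/fibroblast, 172 in conventional dendritic, 54 in T/NK and 16 in plasmacytoid dendritic cells. With no filter on low counts they were 2145 in endothelial, 589 in conventional dendritic, 372 in T/NK and 127 in plasmacytoid dendritic cells. Thinned sums gave 76 in T/NK and 14 in plasmacytoid dendritic cells, and 10% of cells removed as doublets gave 102 and 19. With no doublets removed there were 19 in plasmacytoid dendritic cells, shares of -0.0475 for cholangiocyte and 6.56 for monocyte/macrophage cells, and too few corn oil monocyte/macrophage cells for a test. At most 15% mitochondrial UMIs gave 137 in T/NK cells and a Kupffer share of 1.09, and leaving out endothelial-carrying cells gave 13 in plasmacytoid dendritic cells, where the immediate early list lost its call (-0.23), as did cell cycle in T/NK cells (0.885). An estimated correlation gave 0 lists called in each of the 7 classes. TMM factors on cell numbers gave shares of -0.38 for Kupffer, -0.83 for cholangiocyte, -0.42 for plasmacytoid dendritic (all turned), 0.22 for stellate/fibroblast, -2.61 for T/NK, -1.60 for endothelial and 1.01 for conventional dendritic cells. Counting mixed clusters gave -0.13 for Kupffer, 0.31 for stellate/fibroblast and -0.58 for endothelial cells.

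Without cluster 22, 46 genes were called in monocyte/macrophage cells and 449 differed from Kupffer cells. Turned there were the lists of scar-associated (0.49), Kupffer identity (0.70) and NRF2 genes (0.66). Among the 7 named genes that turned were Blvrb (0.54), Cd5l (0.88), Hspb1 (7.66), Mmp12 (0.955), Srxn1 (1.01) and Txn1 (0.48). Corn oil held no UMI of Hspb1 there, 1 each of Cd5l and Mmp12 and 2 of Srxn1, so these 4 fitted values have no reliable size or direction.

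Leaving out 1 mouse gave 1716 to 3003 genes in Kupffer, 306 to 1430 in endothelial, 1262 to 2350 in monocyte/macrophage, 753 to 1079 in stellate/fibroblast, 127 to 433 in T/NK and 0 to 117 in plasmacytoid dendritic cells. The 0 came from edgeR without CCl4 2. Differences between classes were 383 to 711 (stellate/fibroblast against endothelial) and 1897 to 3111 (monocyte/macrophage against Kupffer). Lists called were 3 to 5 in plasmacytoid dendritic, 2 to 5 in conventional dendritic and 4 to 9 in T/NK cells. Shares ranged from 0.51 to 0.57 (Kupffer), -2.07 to -1.41 (T/NK), 1.61 to 2.39 (conventional dendritic), -0.73 to -0.63 (endothelial), 3.64 to 4.32 (monocyte/macrophage), 0.16 to 1.75 (stellate/fibroblast), 0.19 to 0.94 (plasmacytoid dendritic) and -0.73 to 2.11 (cholangiocyte, turned at -0.73 without corn oil 1 and -0.27 without CCl4 1). The T/NK cell cycle median ranged from -0.96 to 1.76, and its test turned without CCl4 1 (-0.96) and corn oil 2 (0.62). Immediate early genes ranged from -0.81 to 0.0143 in endothelial and from -0.46 to -0.0061 in conventional dendritic cells, both turned without CCl4 2. Inhba in the monocyte/macrophage class ranged from -3.62 to 0.93 (without corn oil 2). Of 326 named calls with values, 229 were kept whichever mouse was left out.

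With the replicate number as a block, 378 genes were called in T/NK, 2261 in endothelial and 75 in plasmacytoid dendritic cells, 5 lists in plasmacytoid dendritic cells, the immediate early list was lost in endothelial (-0.25) and conventional dendritic cells (-0.10), and the conventional dendritic share was 1.99, no longer called. Deviations of mice with the same number correlated by 0.065 to 0.202 across genes, which are not independent replicates, so over all genes the block gives little reason to pair the mice, although Nr1d1 was higher in the first mouse of both groups.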

Other observations

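The tests of cluster 22 and of endothelial-carrying cells used here were chosen after the results had been seen. Changes that kept their call whichever mouse was left out were 54 of 60 named calls in Kupffer, 52 of 60 in monocyte/macrophage, 53 of 65 in stellate/fibroblast, 18 of 25 in conventional dendritic, 16 of 32 in T/NK and 36 of 74 in endothelial cells, and 0 of 10 in plasmacytoid dendritic cells by edgeR.

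Scar-associated genes rose in Kupffer cells (median 2.13), and Mmp12, Gpnmb and Spp1 kept their calls without any 1 mouse. Fry called the list there (adjusted p = 0.02115), but an estimated correlation did not (adjusted p = 0.182). The same list fell in the monocyte/macrophage class (adjusted p = 0.13 with an estimated correlation), but turned to 0.49 without cluster 22, so the opposite directions of the 2 classes may come from the cells that made up the corn oil side. Mmp12 leads cluster 11, which held most CCl4 Kupffer cells, while Marco, Clec4f and Vsig4 lead it and cluster 9, the main corn oil one. Change within cells and replacement of cells both stay open, and which took place was not tested.

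Many of the genes lower in CCl4 outside the endothelium stood at a small part of their level in another class, such as Dcn in Kupffer cells. Endothelial marker RNA was lower in CCl4 in every other tested class. In plasmacytoid dendritic cells, where 13 genes stayed called with endothelial-carrying cells left out, much of the fall may therefore come from RNA of other cells.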
